A study of Mus musculus with 4 samples.

How the data were processed

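Total RNA of cultured dorsal root ganglion neurons was reverse-transcribed and measured with SYBR Green on a commercial array of inflammatory genes, per the labels' protocols. The instrument, the threshold setting and the analysis software are not given in the sources used here. The deposited files are 3 tables, 1 per stimulation, each with raw Ct values of 3 stimulated and 3 untreated arrays, followed by tables of mean Ct, mean ΔCt, fold change and p-value. A Ct is the cycle at which a well crosses the threshold, so a lower Ct is a higher level, and 1 cycle corresponds to a doubling at full PCR efficiency. Efficiency per gene was not measured here and was taken as full for every gene. The 9 control wells are 3 each for genomic DNA, reverse transcription and PCR.

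What the authors computed was checked on the files. The deposited mean Ct values equal the means over 3 arrays after every Ct above 35 and every undetermined well was set to 35, within 0.005 cycles. The deposited ΔCt is headed as relative to housekeeping genes, per the file headers, but its values equal Ct minus the mean of the 9 control wells within 4.4e-07 cycles in all 3 tables, and differ from the ΔCt against the 5 housekeeping genes by a median of 2.61, 2.21 and 2.52 cycles. The deposited fold change is a ratio of stimulated over untreated, 2 to the power of the negative ΔΔCt, which was recomputed with a largest relative difference of 0.00011. The deposited p-value is that of an unadjusted two-sample test of ΔCt with equal variances in all but 2, 3 and 1 wells of the 3 tables. In the authors' deposited tables p is under 0.05 for 110, 76 and 24 panel genes, and 55, 15 and 24 of these are among the genes tested here. The others did not meet the detection rule below in either group. For many of these, such as Ahsg, the authors' deposited tables repeat 1 fold and 1 p-value of that test, 0.964 and 0.0335 with CpG and 0.851 and 0.0177 with gardiquimod. A gene set to 35 on every array gives just these values, which then reflect the control wells alone.

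The plan made before the data were examined was to normalize to the housekeeping genes that the authors' ΔCt uses. As it uses none, the mean Ct of all 5 (Gusb, Hprt1, Hsp90ab1, Gapdh and Actb) was used, and the 9 control wells, which measure genomic DNA, reverse transcription and PCR and no transcript of the cultures, became an alternative. The level of a gene is given as -ΔCt, on a log2 scale, with Ct capped at 35. A gene was detected in a group when its Ct was under 35 on more than 50% of its arrays, and was tested when detected in either group. A fold against untreated arrays that all lie at the cap, with all stimulated arrays below it, is a lower bound and is written as at least. Where only some arrays lie at the cap, the mean takes them as 35.

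Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), on the 6 arrays of a table for each stimulation and on all 12 arrays for differences between stimulations. Gene lists with at least 3 tested members were tested with fry, adjusted over lists. Its test for a single direction asks whether the genes of a list move one way on balance, and its test for either direction whether they change at all, and neither compares a list with other genes. The 11 lists were inflammatory chemokines, homeostatic and lymphoid chemokines, interferons and interferon-induced genes, pro-inflammatory cytokines, T cell and anti-inflammatory cytokines, chemokine receptors, cytokine receptors, Toll-like receptors and adaptors, the NF-kB pathway and stress kinases, and markers of leukocytes and of glia and fibroblasts that such cultures could hold. Some genes are in more than 1 list. The genes named for each stimulation were those past the threshold, the 10 detected genes with the largest log2 change where fewer than 5 passed, a fixed set of cytokines, chemokines and receptors, and the members of each list with the largest change. Genes named with a result of an alternative setting or in the tests of differences were chosen after their values were seen. Ct values of housekeeping genes and control wells were compared by two-sided exact permutation.

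The comparison was tested on simulated data with 60 changed genes. The spread of each gene was limma's estimate, which is drawn from the measured spread toward a common value. For CpG, with 261 genes, 49.4% of genes changed by a log2 of 2 and 97.5% of those changed by 4 were recovered. For gardiquimod, with 248 genes, these shares were 53.7% and 98.2%, and for ODN 1826, with 238 genes, 71.1% and 100%. Changes of 1 were recovered in 6.5%, 6.4% and 11.1% of genes. The changed genes were drawn at random, with independent normal noise and no Ct cap. These shares therefore do not hold for genes of wide spread. With CpG, Ccl5, Cxcl10 and Irf7 changed by a log2 of more than 4 and did not pass.

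The control columns of the 3 tables hold the same 3 arrays, with arrays 2 and 3 exchanged in order in the gardiquimod table. Untreated arrays are numbered here as in the other tables, except in the pairing check, which follows each table. They differ in 3 wells of control array 1. Ccr1 is 33.2 in the CpG table and 32.0 in the others, Myd88 is 37.3 in the CpG table and 33.3 in the others, and Tlr9 is 33.0 in the ODN 1826 table and undetermined in the others. Each comparison used its own table, and the fit over 12 arrays used the value that 2 of the 3 tables give. Whether array numbers pair stimulated with untreated arrays was checked by the correlation of their deviations from the group means. It was 0.116, 0.204 and 0.324 for the 3 pairs of the ODN 1826 table, above the limit set for pairing. For pair 1, though, the best correlation was not with the array of the same number. It was -0.366 and -0.123 for pairs of the CpG table and -0.02 for a pair of the gardiquimod table. The numbers could thus be taken as pairing only in the ODN 1826 table. The main test was unpaired there too, as planned, and the array number as a block was an alternative. Alternatives were other normalizers (each housekeeping gene alone, all genes under Ct 35 on every array, the control wells), other caps and filters, other tests, array weights, 1 fit for all arrays, the array number as a block and leaving out each array. Of the 370 panel genes 363 had an accession in the RefSeq gene table of assembly GRCm38.p6, where 8 carry another symbol, and the array's own symbols are used throughout. The sample titled TLR3 names CpG as its agent in every label, and it was analysed under that title. The tables of mean relative level and of fold regulation repeat other tables and were not used.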

Results

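Dorsal root ganglion neurons were taken from embryos of NIH Swiss mice at day 13 and grown in culture for 4 days with nerve growth factor. From day 5 they were stimulated for 16 h with 1 of 3 agents or left untreated, and the question was which inflammatory transcripts respond to stimulation through Toll-like receptors, the sensors of microbial nucleic acids and other microbial products. The groups were CpG at 25 µg/ml, which its title assigns to TLR3, gardiquimod at 3 µg/ml, a small-molecule agonist assigned to TLR7, and ODN 1826 at 32 µg/ml, a CpG oligodeoxynucleotide assigned to TLR9. CpG DNA is known as a ligand of TLR9, so the first group is named here as its title gives it and no receptor is inferred from it. Transcripts were measured by real-time PCR on arrays that hold wells for 370 panel genes, 5 housekeeping genes and 9 control wells. Each group has 3 arrays, and the same 3 untreated arrays served all 3 comparisons, which makes 12 arrays. The series description speaks of separate studies without saying what was separate, and GEO lists 1 sample per group, so p-values measure only the spread between arrays, which may be technical.

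The untreated cultures gave a threshold cycle (Ct) under 35 for 202, 205 and 231 of the 370 panel genes. CpG arrays gave 257, 255 and 245 such genes, gardiquimod arrays 264, 209 and 257, and ODN 1826 arrays 256, 232 and 209. The number of arrays limits the precision. The mean Ct of the 5 housekeeping genes was 24.3 ± 0.305 (SD, n = 3) in untreated arrays, 23.7 ± 0.541 with CpG, 23.9 ± 1.18 with gardiquimod and 23.8 ± 0.739 with ODN 1826. The differences from untreated arrays of -0.64, -0.416 and -0.518 cycles gave two-sided exact permutation p-values of 0.3, 0.6 and 0.4, where 3 arrays against 3 cannot give less than 0.1. Gapdh, a glycolytic enzyme, differed by -1.13, -0.819 and -1.11 cycles (exact permutation p = 0.1, 0.4 and 0.1). Gusb, a lysosomal enzyme, differed by -0.162, -0.36 and -0.281 cycles (0.8, 0.6 and 0.7 in the same test). The choice of housekeeping gene therefore moved every relative level, as the plot of housekeeping Ct shows. The 9 control wells differed by -0.053, -0.232 and -0.0179 cycles (exact permutation p = 0.1, 0.1 and 0.4). Among them the PCR control wells differed by -0.0232, -0.386 and -0.0425 cycles (0.9, 0.1 and 0.9 in the same test).

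**Figure D1:**
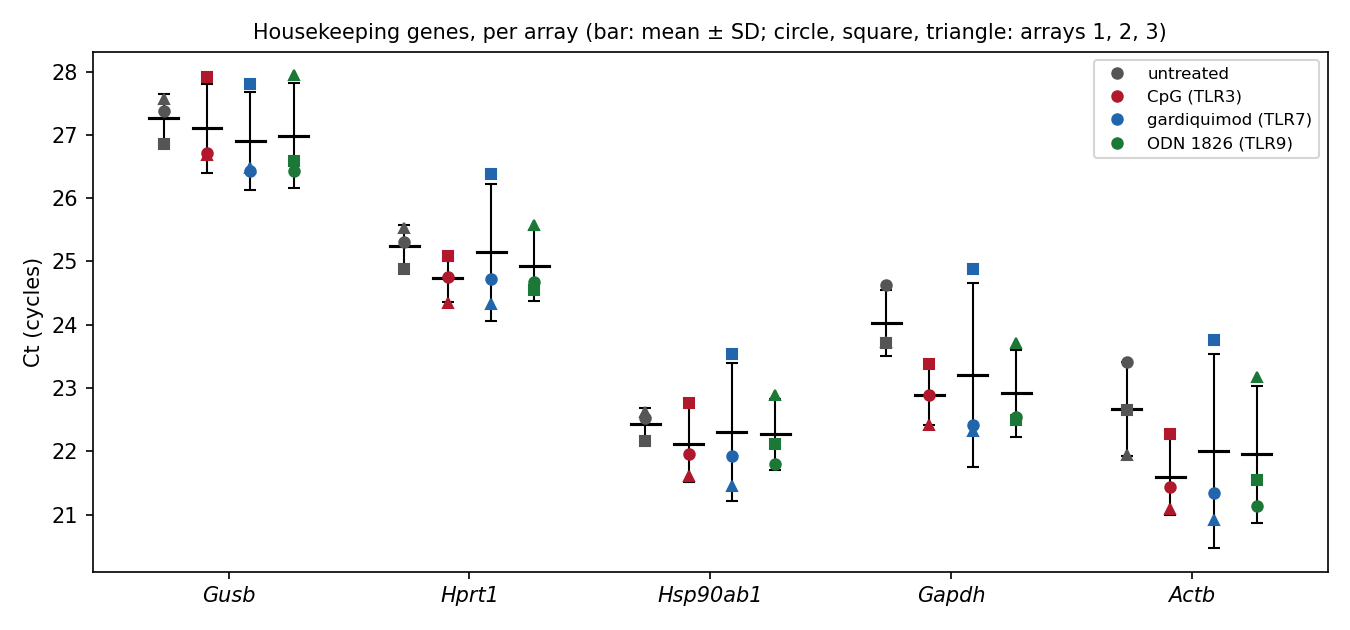
Threshold cycles of the 5 housekeeping genes on each of the 12 arrays, with the gene on the horizontal axis and Ct in cycles on the vertical axis (a lower Ct is a higher level). Colours are groups, symbols are arrays 1 to 3, and bars are the mean ± SD; Gapdh means lay 1.13, 0.819 and 1.11 cycles below the untreated mean, and Gusb means 0.162, 0.36 and 0.281 cycles below it.

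In the cultures given CpG, chemokine and interferon-related transcripts had the highest levels relative to untreated cultures, but they differed widely between the 3 arrays and no gene passed the test. Ccl5, a chemokine for T cells and monocytes, was 59.8-fold higher (log2 change 5.90, SE 1.40, n = 3 arrays per group, limma adjusted p = 0.121). Cxcl10, an interferon-induced chemokine, was 49.1-fold higher (log2 5.62, SE 1.86, adjusted p = 0.194), and Irf7, a transcription factor of the interferon response, 39.4-fold higher (log2 5.30, SE 1.54, adjusted p = 0.143). Cxcl11, a chemokine of the same family as Cxcl10, had no Ct under 35 on any untreated array and was at least 38.4-fold higher. Tlr2, a receptor for bacterial lipoproteins, and C3, the central complement component, were 19.8-fold and 17.7-fold higher, with log2 changes of 4.30 (SE 1.10) and 4.15 (SE 0.899). Cxcl2 and Cxcl5, chemokines for neutrophils, were 15.4-fold and 12.2-fold higher, Ccrl2, an atypical chemokine receptor, 11.8-fold and Ccl4, a chemokine for monocytes, 10.5-fold. Cxcl2, C3, Ccl4 and Cybb had an adjusted p of 0.0859, the lowest of the 261 genes tested by limma. CpG array 3 lay apart in the interferon-related genes, with a Cxcl10 Ct of 32.4 against 24.2 and 26.6 on arrays 1 and 2. The log2 changes without CpG array 3 and without array 1 were 8.20 and 3.91 for Cxcl10, 7.38 and 4.21 for Irf7 and 7.86 and 4.83 for Ccl5. They were 7.92 and 3.76 for Cxcl11, 5.61 and 3.48 for Tlr2, 4.68 and 2.72 for Cxcl5 and 4.69 and 3.10 for Ccrl2. Ccl2, a monocyte chemokine, was 7.06-fold higher and Il1a, an alarm cytokine, 4.47-fold higher, while Il6 was 2.42-fold higher with a Ct of 31.4 ± 0.832 (SD, n = 3). Spp1, which encodes osteopontin, was among the panel genes with the lowest Ct, at 23.8 ± 0.158 with CpG and 23.6 ± 0.855 in untreated arrays.

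The 22 inflammatory chemokines on the panel gave 19 tested genes, of which 18 had a log2 change above 0 and none passed over all genes, while 9 rose when adjusted over the list alone. Their median log2 change was 1.90, against 0.38 for all genes tested. Among the 6 tested interferons and interferon-induced genes the median was 5.28, with 0 past the threshold over all genes and 4 when adjusted over the list alone. For the other lists the corresponding counts adjusted over the list alone were 3 of 9 leukocyte markers (median 0.92), which include Il2rg and Cd86, 1 of 13 cytokine receptors (0.52) and 1 of 7 markers of glia and fibroblasts (0.18). They were 0 of 15 Toll-like receptors and adaptors (0.68), 0 of 4 genes of the NF-kB pathway (0.90), 0 of 13 pro-inflammatory cytokines (0.50), 0 of 7 homeostatic chemokines (0.04, with a mean of -0.20), 0 of 3 chemokine receptors (0.28) and 0 of 3 T cell cytokines (-0.61). The fry test found no list that moved in one direction (lowest adjusted p = 0.0723, leukocyte markers) or changed in either direction (lowest adjusted p = 0.0725). In this comparison 36 genes had an unadjusted p under 0.05, 34 of them higher. Leaving out each array in turn was planned before the data were examined. Without CpG array 3, which stood out only once its values were seen, 37 genes passed, and without any other single array 0 did. With the authors' normalizer, the 9 control wells, 19 genes passed.

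**Figure D2:**
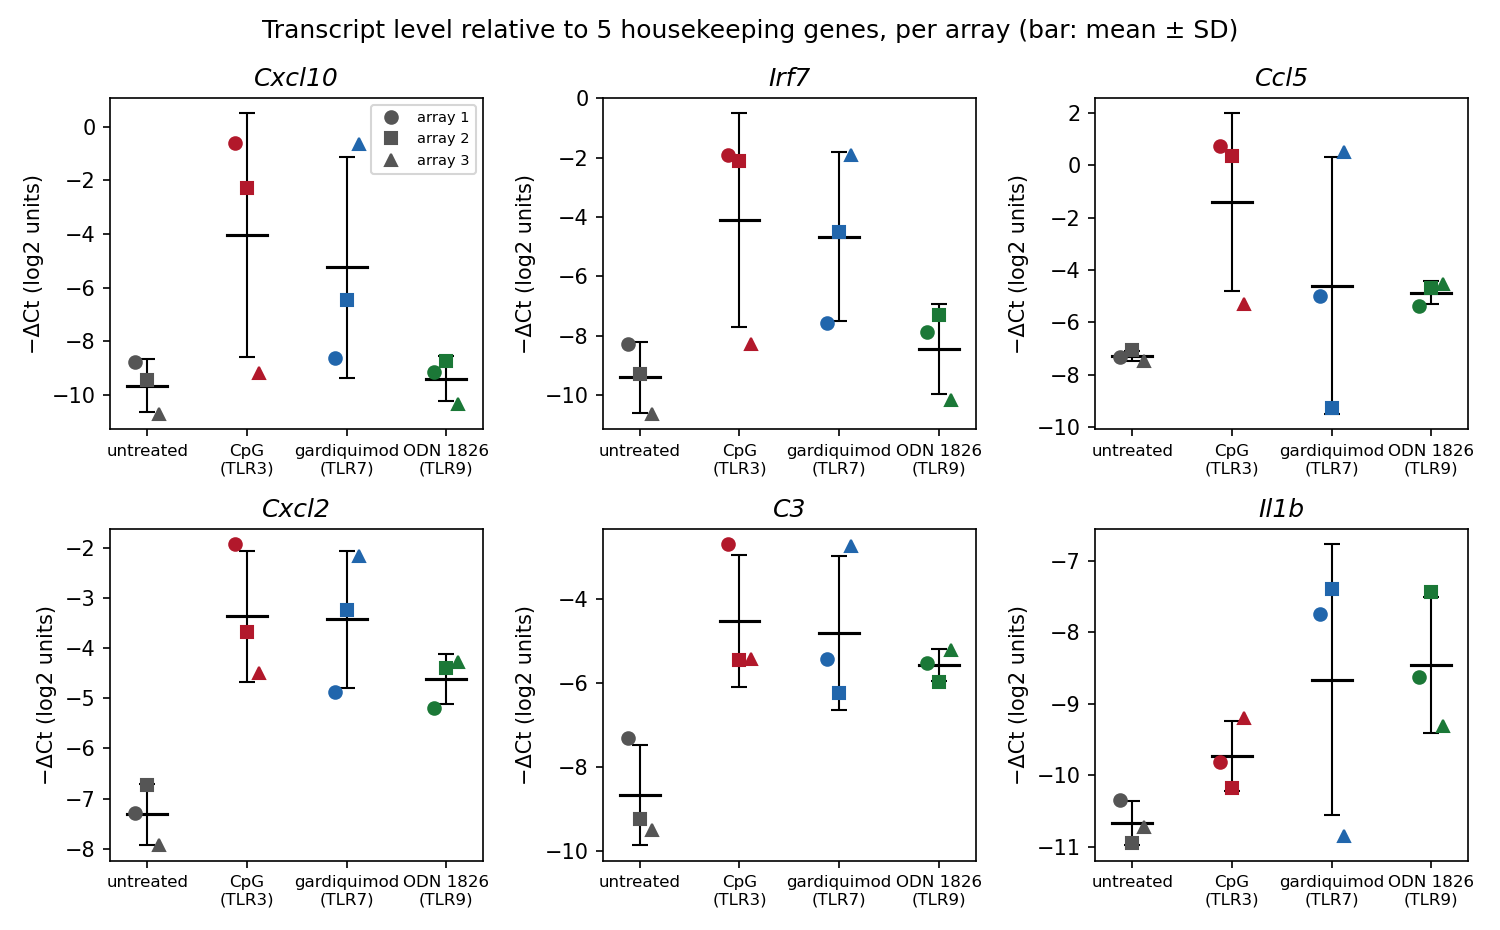
Levels of 6 transcripts on each array relative to the mean of the 5 housekeeping genes (−ΔCt in log2 units, vertical axis) by group (horizontal axis). Symbols are arrays 1 to 3 and bars are the mean ± SD of 3 arrays; Cxcl10 lay at -0.62 and -2.28 on CpG arrays 1 and 2 and at -9.20 on array 3, and wells at or above Ct 35, such as all untreated Il1b wells, are drawn at the cap of 35.

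In the cultures given gardiquimod, Irf7, Cxcl10 and Cxcl11 had the largest mean changes over untreated cultures, followed by Cxcl2, C3 and Tlr2, and no gene passed the test. Irf7 was 26.8-fold higher than in untreated cultures (log2 4.74, SE 1.31, n = 3 arrays per group, limma adjusted p = 0.14), Cxcl10 21.3-fold (log2 4.41, SE 1.75) and Cxcl11 at least 16.2-fold. Cxcl2 was 14.9-fold higher (log2 3.89, SE 0.736, adjusted p = 0.0831), and C3 and Tlr2 were both 14.6-fold higher. Ccrl2 was 8.46-fold higher, Cybb, the catalytic subunit of the phagocyte NADPH oxidase, 8.08-fold (log2 3.01, SE 0.581, adjusted p = 0.0831), Il1a 7.88-fold and Il2rg, the shared gamma chain of interleukin receptors, 6.99-fold (log2 2.80, SE 0.568, adjusted p = 0.0831). Il1b, a pyrogenic cytokine, had no Ct under 35 on untreated arrays and was at least 4.02-fold higher, and Tnf, likewise, at least 2.13-fold. Ccl5 was 6.51-fold higher with an SE of 2.02 on a log2 change of 2.70. Gardiquimod array 3 lay apart in the interferon-related genes, with a Cxcl10 Ct of 23.7 against 32.0 and 31.7 on arrays 1 and 2. Without it the log2 changes were 2.11 for Cxcl10, 2.04 for Cxcl11, 3.36 for Irf7, 3.26 for Cxcl2, 2.84 for C3 and 2.79 for Tlr2. Cxcl10 and Cxcl11 then lay below Cxcl2, C3 and Tlr2, so the order given above rests on that array. The 3 genes that passed without it were Cxcl2, Fpr1 and Il1b. None of the 248 genes tested passed the limma test, and 27 had an unadjusted p under 0.05, all 27 of them higher.

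Among the inflammatory chemokines 17 of 18 tested members had a log2 change above 0 (median 2.04, against 0.36 for all genes tested), 0 passed over all genes and 5 rose when adjusted over the list alone. The 5 tested interferon-related genes had a median of 4.02, and 1 passed when adjusted over the list alone. Without gardiquimod array 3 that median was 2.08, over 4 genes. The leukocyte markers changed in the fry test for either direction (adjusted p = 0.00746), with 9 of 10 above 0, a median of 0.88 and 3 of them higher when adjusted over the list alone. The Toll-like receptors and adaptors changed likewise (adjusted p = 0.0342), with 12 of 13 above 0, a median of 0.94 and none past the threshold alone. No list passed the fry test for a single direction (lowest adjusted p = 0.151). Both list calls were absent with all genes under Ct 35 on every array as the normalizer, with the 9 control wells, and without gardiquimod array 2 or 3 or untreated array 2, and 1 was left without untreated array 1. Adjusted over the list alone, 1 of 12 cytokine receptors (median 0.35) and 1 of 7 markers of glia and fibroblasts (-0.12, with a mean of 0.65) rose, and 0 members did in the pro-inflammatory cytokines (0.45), the homeostatic chemokines (0.30), the NF-kB pathway (0.39), the chemokine receptors (0.27) and the T cell cytokines (-0.15).

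In the cultures given ODN 1826, 4 genes with roles in innate immunity rose in the limma test over 238 genes, and 0 fell. Fpr1 (NM_013521), a receptor for bacterial formyl peptides, rose at least 10.3-fold (log2 3.37, SE 0.647, n = 3 arrays per group, adjusted p = 0.0416). It was detected on all 3 stimulated arrays and on 0 of the untreated arrays. C3 (NM_009778) rose 8.59-fold (log2 3.10, SE 0.627, adjusted p = 0.0447), from a Ct of 33.0 ± 0.933 (SD, n = 3) to 29.4 ± 0.517. Cxcl2 (NM_009140) rose 6.46-fold (log2 2.69, SE 0.505) and Ccl5 (NM_013653) 5.40-fold (log2 2.43, SE 0.449), both with an adjusted p of 0.0416. Each of the 4 was higher on all 3 stimulated arrays than on every untreated array, as were 34 genes in all, while 5 were lower on all, together 16.4% of the genes tested against 10% by chance. That share was 16.5% with CpG and 16.1% with gardiquimod, where 0 genes passed, so it does not set ODN 1826 apart. The 3 comparisons also share their untreated arrays. In assembly GRCm38.p6 Fpr1 lies on chromosome 17 from 17876471 to 17883939, C3 on chromosome 17 from 57203967 to 57228136, Cxcl2 on chromosome 5 from 90903899 to 90905938 and Ccl5 on chromosome 11 from 83525778 to 83530518. Not past the threshold in this unpaired test were Tlr2 at 5.12-fold (adjusted p = 0.111), Ccl4 at 5.06-fold (0.082), Cybb at 4.87-fold (0.082), Il1b at no less than 4.64-fold (0.106), Il1a at 4.49-fold (0.151) and Il2rg at 4.44-fold (0.111). With the array number as a block, an alternative, Tlr2, Ccl4, Cybb, Il1a and Il2rg passed too, and Il1b did not. Cxcl10 was 1.19-fold higher (log2 0.25, SE 0.639) and Irf7 1.94-fold (log2 0.96, SE 0.844). Il6, Ccl7 and Cxcl5 had log2 changes of 0.28, 0.11 and -0.19, each smaller than its SE.

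Of the 18 tested inflammatory chemokines 2 rose (Ccl5 and Cxcl2), 0 fell and 16 did not pass. Adjusted over the list alone 3 rose. The list had a median log2 change of 0.78, against 0.25 for all genes tested, and changed in the fry test for either direction (adjusted p = 0.00191). The 4 tested interferon-related genes (median 0.94, 1 rose, adjusted p = 0.00503), the 8 leukocyte markers (median 0.94, 0 rose, adjusted p = 0.00366) and the 7 markers of glia and fibroblasts (median -0.12, mean 0.46, 1 rose, C3, adjusted p = 0.0114) did so too. Without ODN 1826 array 2, 0 list calls were left, while 2 were left without array 1 and there were 7 without untreated array 3. No list moved in a single direction (lowest adjusted p = 0.0824, inflammatory chemokines). Adjusted over the list alone, 2 of 13 pro-inflammatory cytokines rose (median -0.06, mean 0.16), and 1 of 2 T cell cytokines, Il10, passed with a negative value that gives no measured fall, since all its stimulated wells lay above Ct 35 and it was under 35 on only 2 of the 3 untreated arrays. The medians were 0.44 for cytokine receptors, 0.44 for Toll-like receptors and adaptors, 0.39 for the NF-kB pathway, 0.22 for chemokine receptors and -0.12 for homeostatic chemokines, with 0 members past the threshold. Leaving out any single array left 0 or 1 of the 4 genes past the threshold. With Gapdh alone, Actb alone or all genes under Ct 35 on every array as the normalizer none passed, nor did any in a fit of all 12 arrays or in the adjusted two-sample tests, while with the array number as a block 9 did, the same 4 among them.

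**Figure D3:**
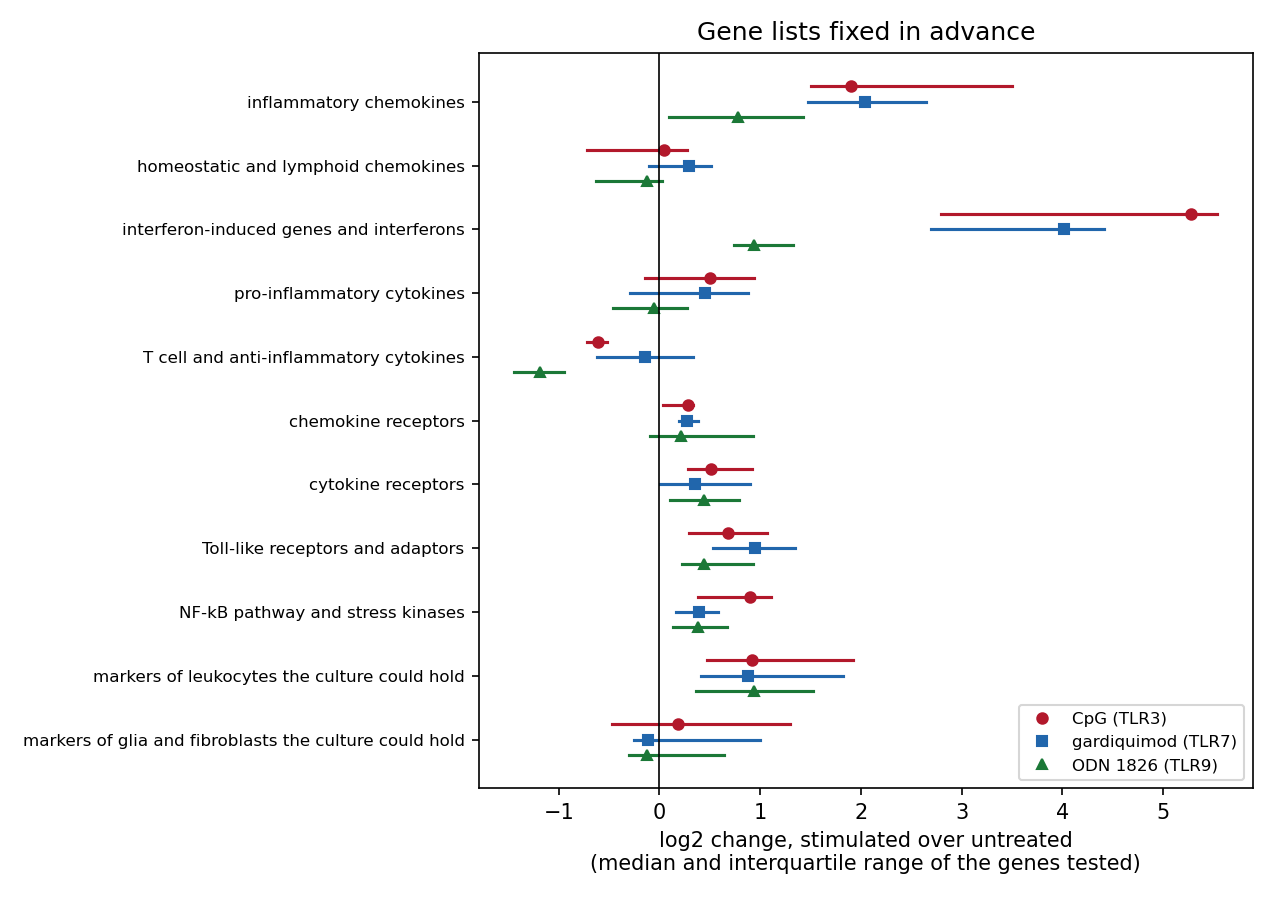
Log2 change over untreated cultures (horizontal axis) for the 11 gene lists (vertical axis), by agent. Points are medians and lines interquartile ranges of the tested genes of each list; the interferon-related list had medians of 5.28 with CpG, 4.02 with gardiquimod and 0.94 with ODN 1826, and of 7.62 without CpG array 3 and 2.08 without gardiquimod array 3.

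The differences between the stimulations themselves were tested in a limma fit over all 12 arrays, with doses of 25, 3 and 32 µg/ml that do not match. No gene passed for CpG against gardiquimod (268 tested, 3 with an unadjusted p under 0.05), CpG against ODN 1826 (260 tested, 14) or gardiquimod against ODN 1826 (252 tested, 8). The lowest p was that of Ccrl2, which was higher with CpG than with ODN 1826 by a log2 difference of 3.72 (SE 0.941, 95% confidence interval 1.67 to 5.78, adjusted p = 0.5). Ccrl2 was also higher with gardiquimod than with ODN 1826 by 3.24 (95% confidence interval 1.19 to 5.29, adjusted p = 0.923). The interferon-related genes differed by a median of 3.90 between CpG and ODN 1826, which did not pass (fry adjusted p = 0.476). Without CpG array 3, 6 genes were higher with CpG than with ODN 1826, and these were Ccrl2, Cx3cl1, Cxcl10, Cxcl11, Ifnb1 and Irf7, but that array was singled out by its low interferon-related transcripts, and without any other single array 0 genes passed. Log2 changes correlated between comparisons across genes, which are not independent replicates, with r = 0.889 for CpG and gardiquimod, 0.628 for CpG and ODN 1826 and 0.665 for gardiquimod and ODN 1826. The first value, and the count of 0 between CpG and gardiquimod, hold for the array labels as given, while array 3 of each of these groups lay apart from its own group. Unchanged groups against shared controls gave 0.494, 0.498 and 0.501 in simulation. The covariances were 1.10, 0.612 and 0.544 against simulated values of 0.248, 0.219 and 0.211. The simulation included the sharing of controls but let genes vary independently of each other. The 3 control arrays cannot be split so that each part keeps 2. Part of the excess may therefore still come from the shared controls.

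The authors' deposited table gives fold changes relative to the 9 control wells and unadjusted p-values. In the authors' deposited table Cxcl10 is 73.8-fold higher with CpG, 24.2-fold with gardiquimod and 1.68-fold with ODN 1826. Recomputed p-values matched the deposited ones within 5e-04 for 382, 381 and 383 wells and differed for 2, 3 and 1. The differing ones were those of Cxcl10, Il1b and Ccl5, and the cause of the difference was not tested. For Cxcl10 the authors' deposited table gives p = 0.0391, 0.0341 and 0.0213 with CpG, gardiquimod and ODN 1826, and the recomputed values were 0.0691, 0.164 and 0.513. For Il1b the authors' deposited table gives p = 0.0455 with CpG and 0.0229 with gardiquimod, against recomputed values of 0.0555 and 0.0629. For Ccl5 with gardiquimod the authors' deposited table gives p = 0.0446, against 0.446.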

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

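The control-well normalizer, the test of ΔCt with it, the fit of 9 stimulated against 3 untreated arrays, and list counts under array blocks or with arrays left out were added after the data were seen; the other alternatives were planned. For CpG the count of genes past the threshold, 0, became 13 with Gusb alone, 7 with Hprt1 alone, 7 with no Ct cap, 1 with a cap of 32, 3 among genes under Ct 35 on every array, 23 with array weights, 6 in 1 fit of 12 arrays, 6 with the array number as a block, 19 with the 9 control wells, 15 in the unadjusted t-test of relative level and 53 in that of ΔCt with the control wells. Without single arrays it ranged from 0 to 37, with 37 only without CpG array 3. For gardiquimod the count of 0 became 1 with a cap of 32, 2 in 1 fit of 12 arrays, 11 and 12 in those 2 unadjusted tests, and 0 to 3 without single arrays (3 without gardiquimod array 3, 1 without array 1). For ODN 1826 the count of 4 became 7 with Hsp90ab1 alone, 0 with Gapdh alone, 0 with Actb alone, 0 with all genes under Ct 35 on every array as the normalizer, 2 with no cap, 9 with no filter, 0 in 1 fit of 12 arrays, 9 with the array number as a block, 0 in both t-tests after Benjamini-Hochberg adjustment, 22 and 23 unadjusted, and 0 to 1 without single arrays; the 1 was Fpr1 without ODN 1826 array 3 and C3 without untreated array 1. Of the 4 genes of ODN 1826, only Fpr1 passed with no cap, beside Il1b. A cap of 32 gave 5 genes and the genes under Ct 35 on every array gave 3, with Fpr1 in neither. Differences between CpG and ODN 1826 ranged from 0 to 6 genes without single arrays, and those of the other pairs were 0 under all alternatives run. The t-tests gave 0 genes after adjustment in all 3 comparisons. The 3 control wells that differ between tables, taken from another table, left the counts at 0, 0 and 4. All 5 housekeeping genes are the chosen normalizer, so that alternative was not run.

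Lists past the test for a single direction, 0 in each comparison, became 6, 1 and 2 with no cap for CpG, gardiquimod and ODN 1826, and 5 for CpG with the control wells; without single arrays they ranged from 0 to 3, 0 to 1 and 0 to 1. Lists past the test for either direction went from 0 to 7 with no cap and 6 with the control wells for CpG (0 to 7 without single arrays), and from 2 to 4 with no cap, 0 with all such genes, 0 with the control wells and 1 with the array number as a block for gardiquimod (0 to 2). For ODN 1826 they ranged from 0 to 7 around 4 without single arrays. The 9 stimulated against 3 untreated arrays gave 7 genes, 16 with Hsp90ab1 alone, 1 with Gapdh alone, 4 with Actb alone, 4 with all such genes, and 2 to 10 without single arrays, with 2 without untreated array 1 or 2. Its lists past the test for a single direction, 4, became 0 with Gapdh alone, 0 with Actb alone, 0 with all such genes, 2 with the control wells and 0 to 5 without single arrays (0 without untreated array 2 or 3, 1 without CpG array 1). The normalizer moved the median log2 change of all tested genes between -0.22 and 0.96 for CpG, -0.14 and 0.68 for gardiquimod and -0.35 and 0.75 for ODN 1826, so small changes have no settled direction. The cause of the other shifts was not tested. Among named genes no called value changed sign under the alternatives run. Counting each gene once per setting, 28 called values under other settings and 22 without single arrays no longer passed. The called genes were only the 4 of ODN 1826, of which 0 or 1 passed when a single array was left out. Of the values that had not passed, 97 under other settings and 41 without single arrays changed sign. Genes near Ct 35 have only bounds, and changes of a log2 of 1 were mostly not recovered in simulated data.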

Other observations

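Of the tests in this part, those of RNA input, of the share of leukocytes, of 2 single arrays and of the splits of 6 arrays, and the fit of all 9 stimulated against the 3 untreated arrays, were chosen only after results were seen, while the splits of the 12 arrays were set before their own result was seen.

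With all 9 stimulated set against the 3 untreated arrays, 7 of 241 genes rose and 0 fell (limma, adjusted p under 0.05), and each was higher on 9 of 9 stimulated arrays than on every untreated array. Cybb, the phagocyte NADPH oxidase subunit, was 6.72-fold higher (log2 2.75, SE 0.393, adjusted p = 0.00199), Cxcl2 11.4-fold (log2 3.51, SE 0.656, adjusted p = 0.0146), Ccl4 higher by a log2 of 2.81 (adjusted p = 0.0182) and C3 13.0-fold (log2 3.70, adjusted p = 0.0203). Ccl9, a macrophage chemokine, was 3.43-fold higher, Il2rg 6.82-fold and Il1a 5.41-fold. By list, the inflammatory chemokines (median 1.69), the cytokine receptors (0.43), the Toll-like receptors and adaptors (0.56) and the leukocyte markers (1.31) passed the fry test for a single direction, upward, each with an adjusted p of 0.0266, against a median of 0.34 for all genes tested. These 4 list calls depend on the normalizer: none passed with all genes under Ct 35 on every array, where the medians were 1.22, -0.05, 0.08 and 0.84 and that of all genes -0.14, and none with Gapdh alone or Actb alone. With the control wells 2 lists passed, without CpG array 1 1 list, and without untreated array 2 or 3 0 lists. Il1b had a Ct under 35 on all 9 stimulated arrays and on 0 of 3 untreated arrays, with a Fisher's exact p of 0.00455 and an adjusted p of 0.64 over 176 genes.

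Of 100 drawn splits of the 12 arrays into 9 and 3, 2 gave as many genes as the real one, itself included. The other of these 2 was the split of CpG arrays 1 and 2 and gardiquimod array 3 against the rest. It gave 43 genes, several times the real 7, and points to a structure of the samples. The fit was chosen after results were seen and the 9 arrays hold 3 agents, so the share does not exclude chance. If the arrays of a group share a culture, the share says nothing of chance between cultures. More RNA in the stimulated arrays, uncorrected by the housekeeping genes, would shift all genes alike. With all genes under Ct 35 on every array as the normalizer the 7 genes kept a median log2 change of 2.30, against 2.77, though 4 genes passed with it, as with Actb alone, 1 with Gapdh alone and 2 without untreated array 1 or 2. A larger share of leukocytes would raise resident markers by about as much, and the leukocyte list fixed in advance, with a median of 1.31, goes with that, but it holds Il2rg and Ccl9, which are among the 7 genes, and Cd14 and Cd86, known to be induced by Toll-like receptors. A set chosen afterwards without such genes, 13 tested of 15, had a median of 0.25 (interquartile range 0.02 to 0.40), against 0.34 for all genes tested. That is below the lower quartile of 2.59 of the 7 genes, but these were chosen for their rise, so most sets would lie below it. Some markers also lay near the cap, such as Syk at a mean Ct of 35 in untreated arrays. As the fixed list rose and this set did not rise beyond the tested genes at large, the share of leukocytes stays undecided. Ct values in this set in untreated arrays were as low as 29.7 for Ly86 and 29.8 for C3ar1, so these transcripts were present in untreated cultures, and a response within such cells or within neurons and glia may account for the 7 genes and stays untested.

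CpG array 3 and gardiquimod array 3 each lay apart from the other arrays of their group. Cxcl10 had a Ct of 24.2, 26.6 and 32.4 on CpG arrays 1 to 3 and of 32.0, 31.7 and 23.7 on gardiquimod arrays 1 to 3, against 33.4, 33.5 and 37.8 in untreated cultures. Fpr1 went the other way, at 33.7, undetermined and 30.2 with CpG and 30.6, 31.2 and 35.3 with gardiquimod. The mean housekeeping Ct values of these 2 arrays lay 0.133 cycles apart, with an SD of 0.832 over the 6 arrays. That argues against a difference in RNA input between the 2, not against one from their own groups. Each had the lowest value of its own group, 23.2 against 23.5 and 24.3 with CpG and 23.1 against 23.4 and 25.3 with gardiquimod. Input relative to the own group is thus not excluded, though Cxcl10 went in opposite directions on the 2 arrays. An exchange of these 2 arrays' labels may be one candidate explanation. Over the 207 genes outside the interferon list, too, each correlated better with both other arrays of the other group than with those of its own. The margin was at least 0.169 (CpG array 3, -0.272 and 0.40 against -0.603 and -0.441). With the list the set held 211 genes, and genes outside the list may vary with those in it. These correlations are therefore no independent evidence of an exchange. For gardiquimod array 3 the values were 0.716 and 0.109 with CpG arrays 1 and 2, -0.309 and -0.40 with its own group and -0.369, -0.288 and -0.571 with ODN 1826 arrays 1 to 3. CpG array 3 points less to gardiquimod, with 0.514, 0.337 and -0.04 for ODN 1826 arrays 1 to 3. Gardiquimod arrays 1 and 2 correlated negatively with each other (-0.159). Within ODN 1826 the values were 0.297 for arrays 1 and 2, -0.0118 for 1 and 3 and -0.143 for 2 and 3. A weak negative value therefore does not show that 2 arrays of a group disagree. Responses that vary between cultures could give such correlations too, so the labels were kept, and no biological explanation was tested.

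For the groups of 3 the splits are too few for a share under 0.05. Where the real count is 0, every split gives as many by definition, so that share holds no information. All 10 of the 10 splits gave at least the real 0 genes for CpG (highest other 1), gardiquimod (highest other 0) and the 3 pairs of stimulations, whose highest others were 29 for CpG against gardiquimod, 2 for CpG against ODN 1826 and 0 for gardiquimod against ODN 1826. The 29 came from CpG arrays 1 and 2 with gardiquimod array 3 against the others, a structure of the samples that the groups do not follow. For ODN 1826 1 of 10 splits, the real one, gave 4 genes (highest other 0, also among the 4 splits that part all pairs).

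Cd40lg, the ligand of CD40 on T cells, had a Ct of 27.4 on CpG array 2 and was undetermined on the other 11 arrays. The lowest Ct of the genomic DNA control wells was 34.9, on untreated array 3.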
